A study of Mus musculus with 4 samples.

How the data were processed

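Total RNA from the mucosa of the nasal septum and turbinates, isolated with TRIzol and labelled with biotin, was measured on 4 Affymetrix mouse gene arrays that cover whole transcripts. The labels give the strain of all mice as C56BL/6. Each of the 4 groups, wild type or Duox2-/- crossed with PBS or flagellin, had 1 array. Whether an array holds RNA of 1 mouse or of a pool is not given in the sources used here, nor are the genome build of the probe sets and the way the Duox2 allele was made.

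The deposited values are on the log2 scale, as their range shows, and per the labels the authors made them with RMA in Affymetrix Expression Console 1.1, which corrects background, equalises the probe distributions of the arrays and summarises each probe set. No further normalisation was applied. The values of the 4 arrays lay between 1.43 and 13.7. Since the background of each probe set is not in the table, low values were read as near background and not as zero expression.

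The table held 35556 probe sets. Of these, 21789 were paired with 1 gene, 1621 with several genes and 12146 with no listed gene. Gene values came from probe sets of 1 gene; for the 999 genes with several such probe sets the one with the highest mean over the 4 arrays was used, which left 19938 genes. Probe sets of several genes or with no listed gene entered a separate count. A gene was ranked and tested if its highest value over the 4 arrays reached 6.52, the median of all values, which 12471 genes did. This level stands for signal over background, and values under it carry less information on differences.

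The comparisons were flagellin against PBS in each genotype, Duox2-/- against wild type in each treatment, and the difference between the flagellin responses. Each was a difference of log2 values with no p-value, since 1 array per group leaves no spread between replicates, and genes were counted at a size of 2-fold. The named genes were the 10 highest and 10 lowest ranked genes of each pairwise comparison, the 8 highest and 8 lowest of the difference, up to 4 members of each list that stood apart, and 15 genes fixed in advance, of which 14 were matched. Predicted genes, olfactory and vomeronasal receptors, immunoglobulin and T cell receptor segments and small RNA genes were left out of the ranking and summarised as families. The rule for named genes, the lists, the comparisons, the tests and most alternatives were chosen before the data were examined.

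The fixed lists were 20 gene lists (signalling, defence, oxidant, stress, clock and cell cycle genes) and 25 cell type marker lists. Of their 569 memberships 521 were matched to a gene and 48 were not, and the latter were not analysed here. A list's median was placed among 10000 random lists of the same size, drawn from genes matched on mean expression in 20 bins, and called apart under the 2.5 or over the 97.5 percentile. This describes the 4 arrays and is not a test of the conditions. Over 220 list comparisons 57 medians were apart above and 54 below, where independent random lists would give 11. The lists share members, genes of a list can vary together and the comparisons share arrays. The 11 is therefore no measure of what chance would give here. In no comparison apart were 7 lists: immediate early genes, the unfolded protein response, thyroid hormone-responsive genes, B and plasma cells, mast cells, Schwann cells and glia, and adipocytes, with medians from -0.21 to 0.44. Lists with fewer than 4 matched genes were given as values.

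Shared responders were genes whose mean response over both genotypes was at least 2-fold, since choosing by 1 genotype favours that genotype through noise alone. The mean avoids this only if the arrays are equally noisy. Over the ranked genes the robust SD of the response was 0.145 in wild type and 0.231 in the arrays labelled Duox2-/-. Choosing by the mean may therefore favour larger responses in the latter. A bootstrap over genes with 2000 draws gave intervals at 95%. These intervals treat the genes as independent, which they are not, and say nothing of the spread between animals or arrays. The additive model, treatment plus genotype, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 7.48 and prior SD 0.136) with Benjamini-Hochberg adjustment at 0.05. It leaves 1 residual degree of freedom, which is the interaction. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene neighbourhoods used positions of GRCm38.p6.

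The steps were tested on simulated data with a noise SD of 0.137. Shifted genes had the same shift in both genotypes, and the noise was independent between genes and arrays. The simulation held no interaction and no tissue difference between arrays, so its rates need not hold for the real arrays. The additive test found 100 of 100 genes shifted by a log2 of 1 and 5 of 12271 unshifted genes. The 2-fold size found 57% of genes shifted by 1, 100% of those shifted by 2 and 0 of 12271 unshifted genes. List placement called 2.5% of unshifted lists apart and 100% of lists shifted by 0.5.

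The alternatives were cyclic loess renormalisation, arrays centred on their median, no filter or a filter at the 75 percentile, a floor at the median, sizes of 1.5-fold and 3-fold, the mean of a gene's probe sets, probe sets of several genes kept, list means and unmatched random lists, responders chosen by each genotype, and a trended robust prior in limma. Chosen after seeing the data were quantile renormalisation, leaving out muscle, squamous, tooth and gland genes, and leaving out the receptors. The genes left out were wider sets of skeletal muscle (38 genes), squamous epithelium (57), tooth enamel and dentine (6) and lateral nasal gland secretions (25). Their medians of the difference between the responses were 1.44, 0.66, 1.40 and -0.26.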

Results

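RNA of the nasal septum and turbinate mucosa was measured in 4 groups of mice, wild type and Duox2-/- by the labels, each given PBS or flagellin through the nose. Flagellin, the protein that builds bacterial flagella, is sensed by a Toll-like receptor of epithelial cells. Duox2 is an NADPH oxidase that releases hydrogen peroxide at epithelial surfaces. The mice were 8 weeks old, the flagellin solution held 5 ug/ml, 25 ul went into each nostril and the tissue was taken after 4 h. Each group had 1 array, so there are no replicates, and this number limits the precision of every value below. The median log2 value was 6.48 in the wild-type PBS array, 6.499 in the wild-type flagellin array, and 6.56 in both arrays labelled Duox2-/-. The interquartile range was 2.79 and 2.73 in the wild-type PBS and flagellin arrays and narrower, 2.54 and 2.43, in the PBS and flagellin arrays labelled Duox2-/-. Across probe sets, which are not independent replicates, Pearson's r was 0.988 between the wild-type arrays and 0.982 between the arrays labelled Duox2-/-. It was 0.979 between the PBS arrays and 0.972 between the flagellin arrays.

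Duox2, the targeted gene, was near background in all 4 arrays and was not lower in the arrays labelled Duox2-/-. Its log2 value was 4.95 in wild-type PBS, 5.12 in wild-type flagellin, 5.23 in PBS labelled Duox2-/- and 5.504 in flagellin labelled Duox2-/-. These values lay at the 23.4, 25.2, 24.4 and 28.4 percentiles of the probe sets of each array. Whether the probe set lies in the altered part of the gene is not given in the sources used here, so the value may check nothing about the genotype. Duox1, the paralog, had log2 values of 5.599, 5.66, 5.75 and 5.69 in the same order, and Duoxa2, the maturation factor of Duox2, had 5.59, 5.88, 5.27 and 5.81.

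Comparing flagellin with PBS in wild-type mice asks which genes the bacterial protein shifts in normal nasal mucosa. Genes for chemokines, inhibitors of NF-kB signalling, antimicrobial proteins and neutrophil products were higher after flagellin. Ccl20, which attracts lymphocytes and dendritic cells, was higher by a log2 difference of 2.48, and Cxcl2, a neutrophil attractant, by 2.43. Tnip3, a feedback inhibitor of NF-kB signalling, was higher by 2.10, Cfb of the complement pathway by 1.91 and Lcn2, which withholds iron from bacteria, by 1.73. The neutrophil granule gene Ngp was higher by 2.97, and Prg2, the major basic protein of eosinophils, by 2.52. The largest difference of a ranked gene was that of Moxd2, a monooxygenase gene related to dopamine beta-hydroxylase, at 5.10.

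Of 12471 genes bright enough to be ranked, 115 were at least 2-fold higher and 7 at least 2-fold lower in the wild-type flagellin array. Of those higher, 50 were olfactory receptor genes, and without the olfactory and vomeronasal receptors the count was 65. Chemokines had a median log2 difference of 0.56, with 14 of 15 genes above 0. NF-kB pathway genes had a median of 0.44 (17 of 18 above 0), with Zc3h12a at 0.90 and Tnfaip3 at 0.82. Antimicrobial and acute phase genes had a median of 0.33, and 7 of 24 were at least 2-fold higher, with S100a8 at 1.83 and the serum amyloid gene Saa3 at 1.13. Cytokines had a median of 0.21, with Il1f9 at 1.53 and Il1b at 1.30, while Tnf was at 0.72, Csf3 at 0.31 and Il6 at 0.01. Only 4 of the 20 cytokine genes were bright enough to be ranked, so this median is less certain. Cxcl1 was at 0.44, Nfkbia at 0.50 and the mucin gene Muc5ac at 0.16. NADPH oxidase and peroxidase genes had a median of 0.26, led by genes of phagocytes: Mpo at 1.14, Cybb at 1.12 and Epx at 1.08. Duox2 itself was at 0.17, Duox1 at 0.06 and Duoxa2 at 0.28. Leukocyte adhesion genes had a median of 0.62, with all 8 above 0, among them Vcam1 at 1.04 and Icam1 at 1.004. Among genes named for any comparison, Saa3, Cxcl1, Tnf, Csf3, Il6, Epx, Mmp8, Epb42, Mx1 and Mx2, as well as Duox2, Duox1 and Duoxa2, were dim, under 6.52 in all 4 arrays, so the sizes of their differences are less certain.

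Markers of several blood-derived cell types were higher in the same array. The neutrophil list had a median of 1.15, and 8 of 13 genes were at least 2-fold higher, including Mmp8 at 1.86 and Retnlg at 1.80. Monocyte and macrophage markers had a median of 0.29, with the chemokine receptor Ccr2 at 1.24. T cell markers had a median of 0.27, dendritic cell markers 0.40 and eosinophil markers 0.59. Of these lists only 1 of 8, 2 of 7 and 1 of 4 genes were bright enough to be ranked, so their medians are less certain. Natural killer cells (0.20), B and plasma cells (0.08) and mast cells (0.04) were not apart from matched random lists. Of the fixed red cell list 3 genes were matched, and Slc4a1, Epb42 and Alas2 were at 1.36, 1.03 and 0.68. Cell cycle genes had a median of 0.45, with all 19 above 0. Muscle and squamous genes were higher in this array too: the skeletal muscle list had a median of 0.80, led by the myosin gene Myh4 at 3.33, and the squamous epithelium list 0.81, led by Krt1 at 2.04. Atp2a1, the calcium pump of fast muscle, was at 2.40 and the myosin gene Myh1 at 2.13, beside Chil3, a chitinase-like gene of myeloid cells, at 2.12 and the gland gene Bpifb9b at 2.498. Without the genes of muscle, squamous epithelium, tooth and gland secretions the counts were 94 higher and 4 lower.

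Genes lower after flagellin in wild type were fewer. Pip, a secreted gland protein, had a log2 difference of -2.29, Jchain, which joins IgA and IgM polymers, of -2.09, the protease gene Klk14 of -1.44 and the secretoglobin gene Scgb2b24 of -1.42. Gucy2c was at -0.99, Cyp2b10 at -0.91 and Agt at -0.90. Ciliated cell markers had a median of -0.18, peroxide-removing enzymes -0.10 and markers of ionocytes and tuft cells -0.23, all apart from matched random lists.

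**Figure D1:**
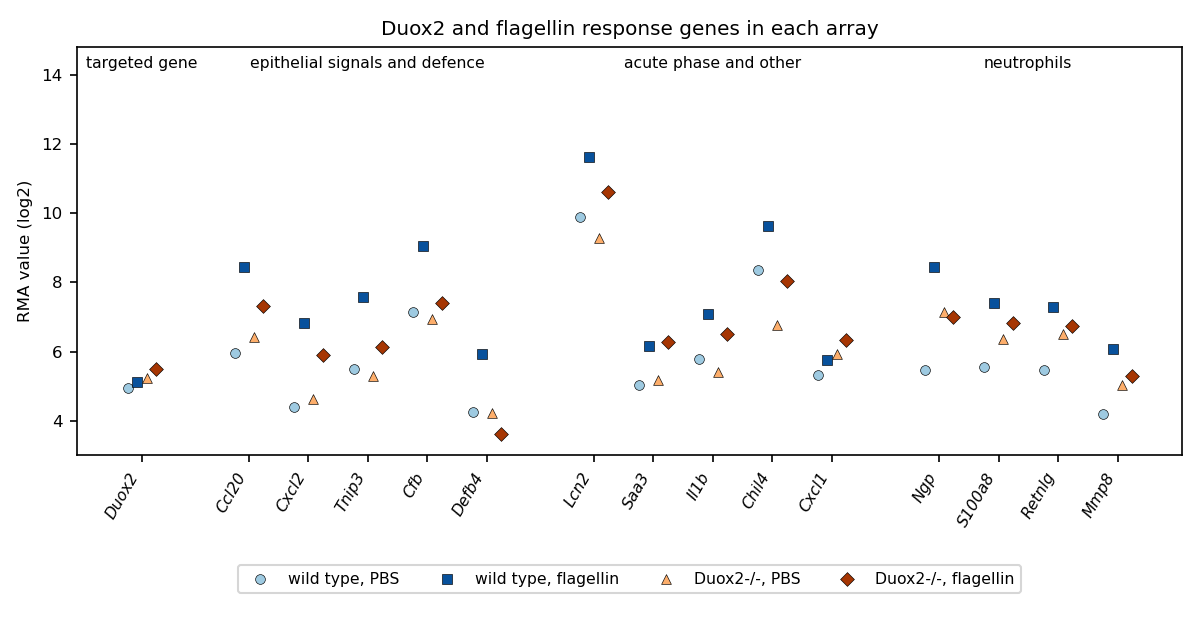
RMA log2 value (vertical axis) of Duox2, the targeted gene, and of 14 response genes in each of the 4 arrays, 1 point per array. Duox2 stays between 4.95 and 5.504, while Ccl20 and Cxcl2 are higher after flagellin in both genotypes, with the highest values in the wild-type flagellin array.

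Comparing flagellin with PBS in the arrays labelled Duox2-/- asks which part of that response is present when the oxidase gene is reported as altered. A smaller set of defence genes was higher. Lcn2 was at 1.32, the chitinase-like gene Chil4 at 1.29, Cxcl2 at 1.26, the acute phase genes Saa3 at 1.12 and Serpina3n at 1.098, and Il1b at 1.09. Moxd2 was again the largest of the ranked genes at 3.67, and Ccl20 was at 0.90. Genes of skeletal muscle and tooth enamel were lower: Myh1 at -3.95, the giant sarcomere protein gene Ttn at -2.79, the enamel matrix genes Ambn at -2.90 and Amelx at -2.31.

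In this comparison 22 genes were at least 2-fold higher and 63 at least 2-fold lower, so that 25.9% of those past the size were higher, against 94.3% in wild type. Without the muscle, squamous, tooth and gland genes the counts were 20 and 41, and without the receptors 12 and 55. Chemokines had a median of 0.23 with 13 of 15 above 0, and antimicrobial and acute phase genes 0.11 with 16 of 24 above 0. NF-kB pathway genes had a median of 0.11 and neutrophil markers 0.18, neither apart from matched random lists; Nfkbia was at -0.25. Cxcl1 was at 0.41, Csf3 at 0.39, Tnf at 0.35, Il6 at 0.20 and Muc5ac at -0.76, and Duox2, Duox1 and Duoxa2 were at 0.28, -0.06 and 0.54. Secretory cell markers had a median of 0.31, with Bpifb1 at 0.89. Mucus genes had a median of 0.16. All 13 olfactory neuron markers were above 0, with a median of 0.35.

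Several tissue, epithelial and myeloid lists were lower in the flagellin array labelled Duox2-/-. Skeletal muscle had a median of -0.996 with 0 of 10 above 0, endothelium -0.58, fibroblasts -0.46, smooth muscle -0.42, squamous epithelium -0.39, basal cells -0.32, cartilage and bone -0.31 and monocytes and macrophages -0.25. Examples were the smooth muscle myosin Myh11 at -1.22, the matrix gene Dpt at -1.18, the basal keratin gene Krt5 at -1.12 and the vessel gene Emcn at -0.96. Bacterial sensors had a median of -0.09, with Tlr4 at -0.84 and its partner Ly96 at -0.68. Not all members shared this: Cd14 was at 0.86, and 9 of 23 genes were above 0. Glucocorticoid-induced genes had a median of -0.38. A predicted gene outside the ranked set, 5430401F13Rik, chosen after its values were seen, was at 3.78 in this comparison and at 0.13 in wild type.

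**Figure D2:**
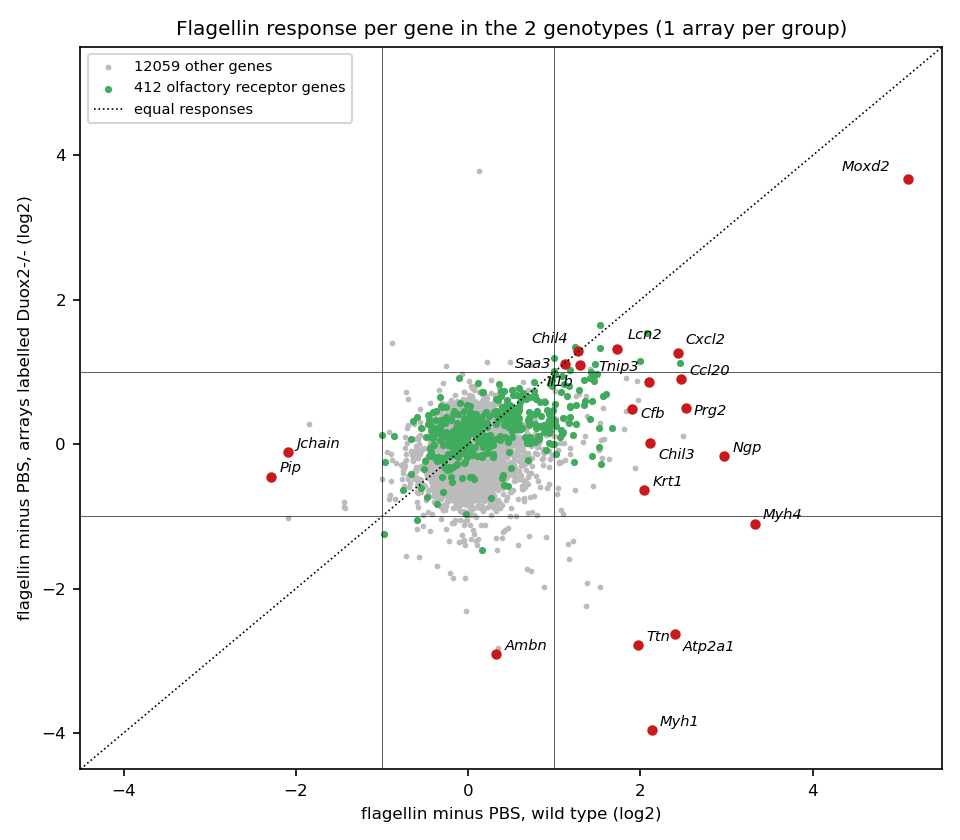
Flagellin response of each of the ranked genes in wild type (horizontal axis) and in the arrays labelled Duox2-/- (vertical axis), log2 flagellin minus PBS, 1 array per group; lines mark 2-fold, and green points are olfactory receptor genes. Moxd2, Lcn2, Cxcl2 and Chil4 lie past 2-fold in both, Ngp and Ccl20 past it in wild type only, and Myh1 and Ttn have opposite signs.

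The difference between the flagellin responses asks whether the response of the arrays labelled Duox2-/- was smaller than that of wild type. Several chemokine and defence genes had a larger response in wild type. The wild-type response exceeded the other by a log2 difference of 1.58 for Ccl20, 1.42 for Cfb, 1.23 for Tnip3 and 1.17 for Cxcl2. It exceeded it by 3.13 for Ngp and 1.60 for Retnlg, and all 13 neutrophil markers leaned the same way, with a median of 0.94. The difference was 0.20 for Il1b, 0.41 for Lcn2 and, among dim genes, 0.01 for Saa3 and 0.03 for Cxcl1. The largest differences belonged to muscle genes, at 6.08 for Myh1, 5.03 for Atp2a1 and 4.76 for Ttn.

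The signed difference, wild-type response minus that of the arrays labelled Duox2-/-, was at least 2-fold above 0 for 180 genes and below 0 for 17; without the muscle, squamous, tooth and gland genes these were 133 and 14. A positive difference is not always a larger wild-type response: of the 180, the wild-type response was the larger in size for 86 and that of the arrays labelled Duox2-/- for 94, and 140 had opposite signs. Lists with a positive difference and a larger wild-type response included chemokines (median 0.31, 12 of 15 above 0), NF-kB pathway genes (0.38, 15 of 18), antimicrobial genes (0.32, 17 of 24) and leukocyte adhesion genes (0.49, 8 of 8). Cytokines did not share this. Their median response was 0.21 in wild type and 0.21 in the arrays labelled Duox2-/-. The median difference was -0.03, with 10 of 20 above 0, and was not apart from matched random lists. The difference was also positive where the responses had opposite signs: 0.57 for monocytes and macrophages, 1.17 for squamous epithelium, 0.78 for fibroblasts and 2.20 for skeletal muscle. For fibroblasts (0.25 and -0.46) and skeletal muscle (0.80 and -0.996) the response of the arrays labelled Duox2-/- was the larger in size. Nfkbia differed by 0.76, Muc5ac by 0.92, Tnf by 0.37, Csf3 by -0.08 and Il6 by -0.18, and Duox2, Duox1 and Duoxa2 by -0.11, 0.12 and -0.26. The difference was negative for Jchain (-1.98), Pip (-1.84), the histone gene H1f3 (-1.45) and the gland gene Dcpp1 (-1.04). Secretory cell markers had a median of -0.34, mucus genes -0.20 and olfactory neuron markers -0.19. For nasal glands the median was -0.17 and the mean 0.12, of opposite sign.

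Both responses shared 14 genes at least 2-fold higher, where 0.203 would overlap if the responses were independent. These were Moxd2, Lcn2, Cxcl2, Il1b, Chil4, AW112010 and 8 olfactory receptor genes. The 0.203 takes all genes as equally likely to pass. Olfactory receptors passed more often, with 50 of 412 ranked ones in wild type and 10 of 412 in the arrays labelled Duox2-/-, so it is too low. Of the 115 genes higher in wild type, 81 had the same sign in the arrays labelled Duox2-/- and 10 were at least 2-fold lower there. Across 12471 genes, which are not independent replicates, the responses correlated with Pearson's r of 0.126. Among 44 genes whose mean response over both genotypes was at least 2-fold higher, the wild-type response was the larger in 38. Their median response was 1.57 in wild type and 0.92 in the arrays labelled Duox2-/-, with a median difference of 0.77 per gene (bootstrap interval over genes 0.495 to 1.12). Without the olfactory receptors it was 1.36 over 23 genes (0.92 to 1.60). Without muscle, squamous, tooth and gland genes it was 0.55 over 40 genes (0.44 to 0.99). Both alternatives were chosen after seeing the data. The intervals are over genes and do not measure the spread between animals. When the genes were chosen by the response of the arrays labelled Duox2-/- alone, the median difference was 0.07, with the wild-type response larger in 11 of 22, and -0.19 over the 12 that were not receptors. Among 14 genes lower by the mean of both responses the difference was 0.55, with an interval of -0.64 to 1.67, and it depended on the setting: -1.06 when genes were chosen by wild type, 1.43 when chosen by the arrays labelled Duox2-/-, 0.90 after cyclic loess, 0.89 after quantile renormalisation, 0.27 without the tissue genes and 0.15 without the receptors.

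**Figure D3:**
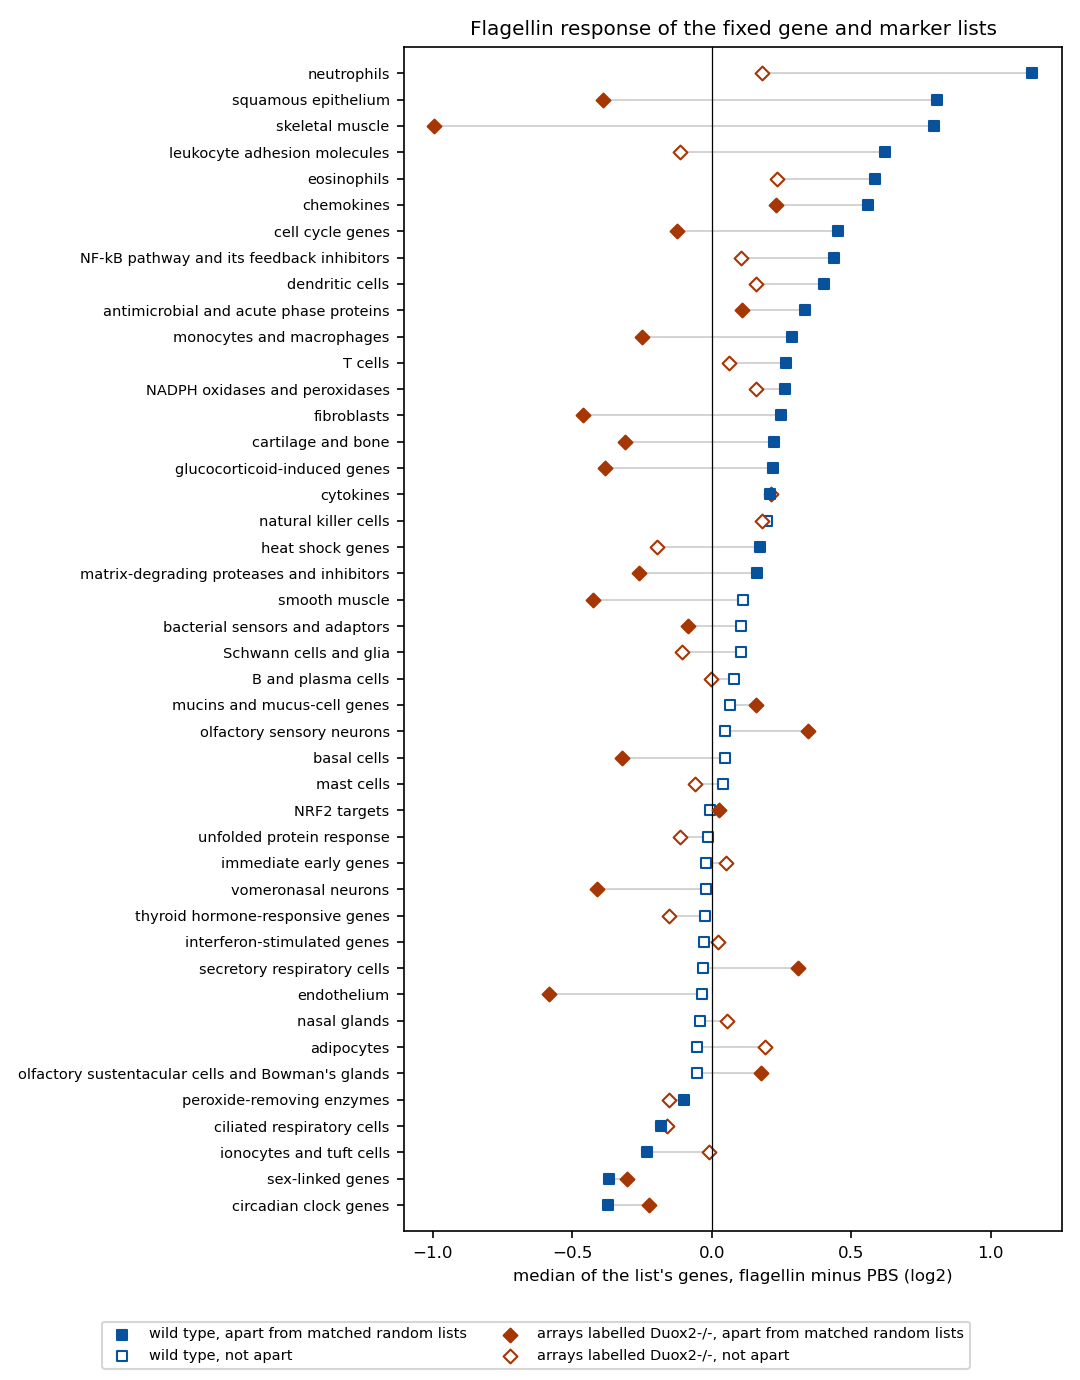
Median log2 flagellin response of the genes of each fixed list with at least 4 matched genes, in wild type (squares) and in the arrays labelled Duox2-/- (diamonds); filled symbols lie outside the central 95% of matched random lists. Of the lists shown, neutrophils, squamous epithelium and skeletal muscle lead in wild type, where skeletal muscle is at 0.80 against -0.996 in the arrays labelled Duox2-/-.

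An additive limma model, with a flagellin shift common to both genotypes and a genotype shift common to both treatments, tested 12471 genes. Flagellin raised 30 genes and lowered 5 at an adjusted p of at most 0.05, against 0 and 0 after cyclic loess (687 at an unadjusted p under 0.05, lowest adjusted p 0.0922), so these calls depend on the normalisation. Moxd2 rose by 4.39 on the log2 scale (adjusted p = 0.00172), Cxcl2 by 1.85 (0.0242), Lcn2 by 1.52 (0.00988), Chil4 by 1.28 (0.0101), AW112010 by 1.23 (0.0220) and Il1b by 1.20 (0.0173). Plekhs1, chosen after its values were seen, rose by 1.38 (0.0399). The other 23 genes that rose were olfactory receptors. The 5 that fell, of which those not ranked were also chosen after their values were seen, were Gm5154 at -1.56, Scgb2b24 at -1.16, 2310057J18Rik at -1.15, Klk14 at -1.12 and Olfr1002 at -1.11. Genes that missed the threshold included Icam1 at 0.87 (adjusted p = 0.0523), Serpina3n at 0.91 (0.0523), Tnip3 at 1.479 (0.0708) and Ccl20 at 1.69 (0.0925).

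By list, 1 of 8 chemokines tested passed for flagellin over all genes, and 6 when adjusted over the list alone. For antimicrobial genes these counts were 1 of 15 and 8 adjusted over the list alone, for neutrophil markers 0 of 7 and 6 adjusted over the list alone, and for NF-kB pathway genes 0 of 15 and 2 adjusted over the list alone. In limma with all genes, 805 had an unadjusted p under 0.05 for flagellin. The interaction is the error term of this model, so it cannot test whether the responses differ.

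Comparing the PBS arrays asks how the mucosa labelled Duox2-/- differed from wild type before any flagellin. Genes of muscle and tooth, and some genes of gland secretions, were far higher in the array labelled Duox2-/-. The nasal gland genes Bpifb9a and Bpifb9b were higher by log2 differences of 6.77 and 6.57, Bpifb5 of the same family by 3.91 and the lipase gene Lipf by 3.01. Gland secretion genes as a wider set did not share this, with a median of -0.04 over 25 genes, 7 of them past 2-fold, and the odorant-binding protein gene Obp1a at -0.08. Myh1 was higher by 4.41, Ambn by 4.38, Myh2 by 3.58, Ttn by 3.26, Amelx by 3.23 and Atp2a1 by 3.18. Genes of interferon responses, of NRF2, the regulator of oxidant defence, and of mucus were lower.

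At least 2-fold higher were 141 genes and lower 35; without the olfactory and vomeronasal receptors 63 were higher, and without the muscle, squamous, tooth and gland genes 107. Of the genes past the size 80.1% were higher, 69.4% when the arrays were centred on their medians and 64.3% without the receptors. All 17 NRF2 targets were below 0, with a median of -0.41, among them Cbr3 at -0.82 and Aox1 at -0.61. Peroxide-removing enzymes had a median of -0.25, with the glutathione peroxidase gene Gpx2 at -1.15 and the catalase gene Cat at -0.56. Interferon-stimulated genes had a median of -0.40, with Mx1 at -1.61, Ifit3 at -1.15 and Mx2 at -0.97. Mucus genes had a median of -0.31, with Tff2 at -0.88 and Muc5b at -0.78. Bacterial sensors had a median of -0.21, with Cd14, a co-receptor for bacterial lipopolysaccharide, at -1.23. Markers of surface epithelium were lower in the same array: sustentacular cells and Bowman's glands had a median of -0.26 with 0 of 8 above 0, ciliated cells -0.24, secretory cells -0.22 and squamous epithelium -0.21. Natural killer cell markers, at -0.03, were also apart below matched random lists. Jchain was at -2.38, the serine protease gene Tmprss11a at -2.03, Serpina3n at -1.63, Chil4 at -1.61, Adh6a at -1.53 and Ifi202b at -1.37.

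Other tissue lists were higher in the PBS array labelled Duox2-/-: skeletal muscle at 1.52 with 10 of 10 above 0, cartilage and bone at 0.64, smooth muscle at 0.50, nasal glands at 0.45 and fibroblasts at 0.44. Neutrophil markers were at 0.47, with Ngp at 1.68, and the vomeronasal neuron list at 1.003. Glucocorticoid-induced genes were at 0.41, with Zbtb16 at 1.38 and Fkbp5 at 0.99, and cell cycle genes at 0.35. The always-named genes all differed by less than 2-fold: Cxcl1 by 0.61, Lcn2 by -0.60, Ccl20 by 0.45, Muc5ac by -0.41, Il1b by -0.39, Csf3 by 0.37, Tnf by 0.32, Duoxa2 by -0.32, Duox2 by 0.27, Cxcl2 by 0.24, Duox1 by 0.15, Saa3 by 0.13, Il6 by -0.13 and Nfkbia by -0.07. For Duox2 this was 0.04 after cyclic loess.

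**Figure D4:**
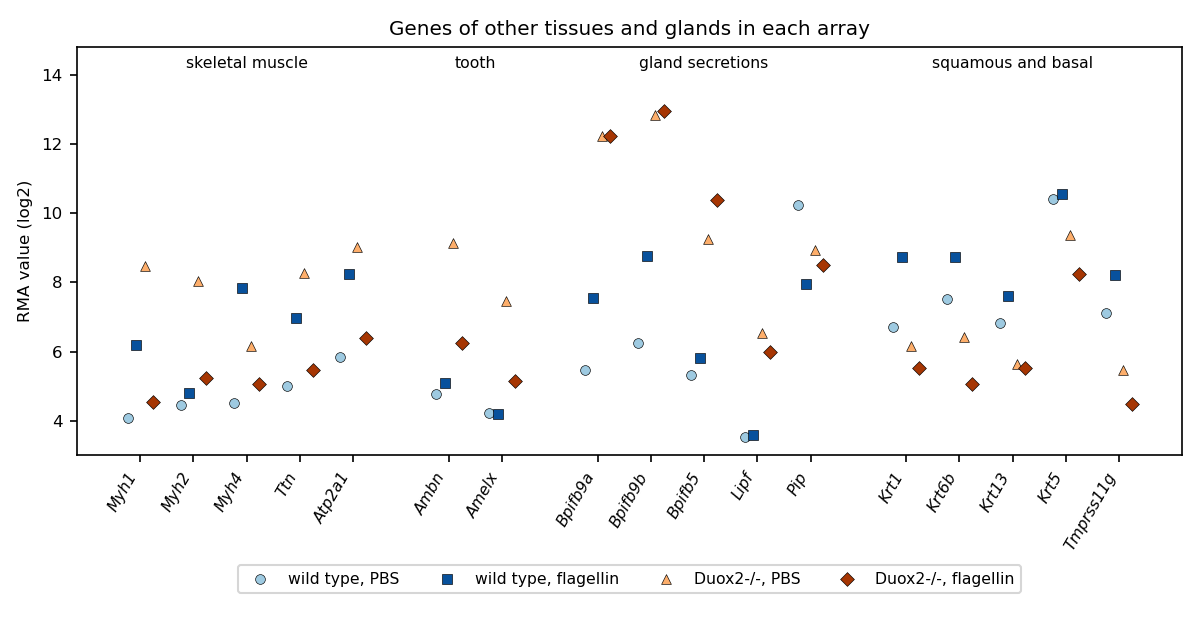
RMA log2 value (vertical axis) of genes of skeletal muscle, tooth, gland secretions and squamous or basal epithelium in each of the 4 arrays, 1 point per array. The muscle genes are highest in the wild-type flagellin array or the PBS array labelled Duox2-/-, and Bpifb9a and Bpifb9b are highest in both arrays labelled Duox2-/-.

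Comparing the flagellin arrays asks how the treated mucosa of the genotypes differed. Genes of squamous and basal epithelium, chemokines and antimicrobial proteins were lower in the array labelled Duox2-/-. The protease gene Tmprss11g was at -3.71, the keratin genes Krt6b at -3.66 and Krt1 at -3.22, and Ifi202b at -3.14. Cfb was at -1.64, Tnip3 at -1.44, Cxcl16 at -1.29, Ccl20 at -1.13, Lcn2 at -1.01 and Cxcl2 at -0.93. Some gland genes were higher, with Bpifb9a at 4.68, Bpifb5 at 4.56, Bpifb9b at 4.18 and Lipf at 2.40.

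Lower by at least 2-fold were 206 genes and higher 44, or 175 and 34 without the muscle, squamous, tooth and gland genes. Squamous epithelium had a median of -1.60 with 9 of 12 at least 2-fold lower, and basal cells -0.64, with Krt5 at -2.29. Chemokines had a median of -0.57 (5 of 15 at least 2-fold lower), NF-kB pathway genes -0.52, antimicrobial genes -0.39 (8 of 24) and bacterial sensors -0.30, with Tlr4 at -1.46. Leukocyte adhesion genes had a median of -0.66, with the integrin gene Itgam at -1.72. Monocytes and macrophages were at -0.55, with Ccr2 at -2.002, endothelium at -0.60, neutrophils at -0.49 and skeletal muscle at -0.35. NRF2 targets were at -0.43, heat shock genes at -0.42 and interferon-stimulated genes at -0.31. Nasal glands were at 0.76 and olfactory neuron markers at 0.17. Muc5ac was at -1.33, Nfkbia at -0.83, Il1b at -0.59, Cxcl1 at 0.58, Csf3 at 0.45, Saa3 at 0.12, Il6 at 0.05 and Tnf at -0.05, and Duox2, Duox1 and Duoxa2 at 0.38, 0.03 and -0.07. For Duox2 this was 0.08 after cyclic loess.

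Across genes the genotype difference correlated between the treatments with Pearson's r of 0.530, against 0.126 for the flagellin difference between the genotypes, but the overlap of higher genes did not favour the genotype difference, and neither contrast was tested. At least 2-fold lower in both PBS and flagellin arrays were 22 genes, against 0.578 if independent, and 20 were higher in both, against 0.497, beside the 14 higher after flagellin in both genotypes, against 0.203. Lower after flagellin in both genotypes was 1 gene, against 0.0354. These values for independence take all genes as equally likely to pass, which the receptors were not. Without the receptors the overlaps of higher genes were 8 for genotype and 6 for flagellin. In the additive limma model 298 genes were higher and 247 lower in the arrays labelled Duox2-/-, against 1 and 0 after cyclic loess (2340 at an unadjusted p under 0.05), so the adjusted p-values that follow depend on the normalisation. Bpifb9a was higher by 5.72 (adjusted p = 0.000865), Bpifb9b by 5.38 (0.00196), Bpifb5 by 4.24 (3.84e-05) and Lipf by 2.70 (0.000635). The log2 difference was -2.68 for Tmprss11g (adjusted p = 0.0137), -2.45 for Tmprss11a (0.00196), -2.25 for Ifi202b (0.0152) and -1.98 for Adh6a (0.00630). It was -1.60 for Chil4 (0.00196), -1.45 for Serpina3n (0.00614), -1.17 for Gpx2 (0.00653) and -1.17 for Ifit3 (0.00653). Among NRF2 targets 4 of 17 passed and 13 passed when adjusted over the list alone, all lower over all genes tested. Among interferon-stimulated genes these were 5 of 13 and 8 adjusted over the list alone, among bacterial sensors 4 of 11 and 7 adjusted over the list alone, and among nasal gland genes 4 of 8, all higher, and 4 adjusted over the list alone. Genes within 10 Mb of Duox2 (160 genes, positions from GRCm38.p6) had a median absolute genotype difference of 0.132 in the PBS arrays, at the 19.4 percentile of other stretches of the genome, and of 0.219 in the flagellin arrays, at the 33.8 percentile. Within 20 Mb (222 genes) it was 0.143 in the PBS arrays and 0.230 in the flagellin arrays, at the 33.6 and 54.1 percentiles.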

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

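Of the tests in this part, only the quantile renormalisation of the difference over all shared responders was set before its result was seen; the other tests of explanations were chosen after.

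Some groups of genes moved in opposite directions after flagellin in the 2 genotypes, and these differences were not tested, for lack of replicates. In wild type and in the arrays labelled Duox2-/-, the medians were 0.22 and -0.38 for glucocorticoid-induced genes, 0.45 and -0.13 for cell cycle genes, and 0.16 and -0.26 for matrix-degrading proteases and inhibitors. For squamous epithelium they were 0.81 and -0.39, for monocytes and macrophages 0.29 and -0.25, for fibroblasts 0.25 and -0.46, for skeletal muscle 0.80 and -0.996, and for cartilage and bone 0.22 and -0.31. Single muscle genes did the same: Myh4 at 3.33 and -1.10, Atp2a1 at 2.40 and -2.63, Myh1 at 2.13 and -3.95, Ttn at 1.97 and -2.79, Tnnt3 at 1.37 and -2.24, Myl1 at 1.53 and -1.98, and Neb at 1.38 and -1.92.

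The genotype difference also had opposite signs in the PBS and flagellin arrays for some groups, again not tested. Cell cycle genes were at 0.35 and -0.21, neutrophil markers at 0.47 and -0.49, and skeletal muscle at 1.52 and -0.35. Myh1 was at 4.41 and -1.67, Ttn at 3.26 and -1.501, Atp2a1 at 3.18 and -1.85, Myh4 at 1.65 and -2.78, and the granule gene Ngp at 1.68 and -1.45.

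Probe sets outside the gene comparisons were counted too. Of 939 with several genes, 3 were at least 2-fold higher after flagellin in both genotypes. Independent responses with all probe sets equally likely to pass would give 0.0639. All 3 belonged to olfactory receptors, among them Olfr1196 and Olfr1197. Of 5018 with no listed gene, 0 were at least 2-fold higher in both, with 23 higher in wild type and 28 in the arrays labelled Duox2-/-. At least 2-fold lower were 21 of these in wild type and 101 in the arrays labelled Duox2-/-, and 3 and 24 of those with several genes.

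The smaller flagellin response in the arrays labelled Duox2-/- concerns the shared responders that were higher. Among the 14 that were lower, the median response was -0.85 in wild type and -1.40 in the arrays labelled Duox2-/-, not smaller in size. The wider spread of responses in the arrays labelled Duox2-/- may add to this, since genes were chosen by the mean. Over the 44 higher ones the median difference was 0.77. After quantile renormalisation it was 0.5001, with an interval of 0.280 to 0.792 across the bound of 0.387, and over genes other than receptors it was 1.08 against 1.36 before, with an interval of 0.506 to 1.22 across the bound of 0.679. The rule set beforehand used only the median of all higher responders, and that median stayed above its bound, against a narrower value range as the cause. The intervals were not part of that rule, and both cross their bounds. They are over genes and do not measure the spread between animals. With them, a narrower value range of the arrays labelled Duox2-/- cannot be told apart from a smaller response in either set. Most of the difference of the non-receptor genes stayed. For the neutrophil genes, marrow precursor genes had a median difference of 0.315 (0.0759 to 0.581), against 0.861 for mature neutrophil genes and 0.624 for erythroid genes. Carried bone marrow cannot be told apart from recruited neutrophils by these values. The erythroid genes cannot decide it. Between the flagellin arrays their median difference, Duox2-/- minus wild type, was 0.08, so their 0.624 reflects a low wild-type PBS array. The wild-type PBS array was also lower than the PBS array labelled Duox2-/- in red cell genes (median gap 0.78 over 8 genes) and neutrophil markers (0.47). What a low wild-type PBS array adds to the difference of the shared responders and of the neutrophil genes was not tested. The Duox2 genotype, tissue carried over in some arrays and variation between animals stay open, as untested with 1 array per group.

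Skeletal muscle genes were high in the wild-type flagellin array and in the PBS array labelled Duox2-/-, which share neither genotype nor treatment. Of 30 muscle genes outside the fixed list, 90% (Wilson interval 74.4% to 96.5%) had a positive difference between the responses. The interval treats the genes as independent, which they are not, and says nothing of the spread between animals. A positive difference holds for muscle carried over at dissection and for a change of muscle RNA alike, so both stay open. Across 38 muscle genes, which are not independent, the excess of the wild-type flagellin array over wild-type PBS correlated with that of PBS over flagellin in the arrays labelled Duox2-/- at r = 0.658, neither high nor low enough to tell whether both arrays held 1 muscle type. No biological explanation was tested.

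Olfactory receptor genes were higher after flagellin in both genotypes, with medians of 0.25 in wild type and 0.17 in the arrays labelled Duox2-/- over 1015 genes. Over the 412 bright enough to be ranked the order was reversed, with medians of 0.14 and 0.21. In wild type a shift of all dim probe sets is argued against, since of 4 other classes of probe sets of the same level small RNA genes moved the other way (-0.117 of the receptors' shift) and the rest by at most 0.0707 of it; in the arrays labelled Duox2-/- it cannot be told apart, since the ratio was 0.0488 for unlisted probe sets but 0.694 for predicted genes and 0.880 for small RNA genes. In those arrays olfactory neuron markers had a median of 0.346, as more olfactory neurons in the sample could give. There class I receptors of the dorsal zone moved with the others (0.184, interval over genes 0.137 to 0.227), which argues against a more ventral sample. A more dorsal one cannot be told apart, since the class I shift was 1.1004 times that of the others. The dorsal and ventral zone genes, 4 each, had medians of 0.13 and -0.33. They did not move together within a set, with ranges of -0.09 to 0.25 and of -0.40 to 0.30, the last for Ncam2. In wild type the neuron markers were at 0.0486 with an interval across the bound, so more neurons cannot be told apart there, while class I receptors were at -0.0644, as a more ventral sample could give, and their ratio to the others of -0.216 argues against a more dorsal one. Across receptors the shifts correlated between the genotypes at r = 0.409 (other genes 0.0415). Receptors with larger flagellin shifts also had larger genotype differences, at r = 0.561 (other genes 0.355). The flagellin and genotype differences share arrays, which can give a correlation by itself. Whether a change that receptors share is particular to flagellin therefore cannot be told.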

How the results depend on the processing

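The alternatives with quantile renormalisation, without tissue genes or without receptors were chosen after seeing the data. Of 111 list medians apart, 105 were also apart after cyclic loess, 103 by the mean of members and 100 against unmatched random lists, and none of the loess values had the opposite sign. By the mean, NRF2 targets in the arrays labelled Duox2-/- after flagellin turned to -0.035 and nasal glands in the difference to 0.12. Of 203 values of named genes past 2-fold, 189 stayed past it after loess and 110 with a floor at the median, so low signal limits many of the sizes. Unless the setting itself changes the size or the number of genes, the cause was not tested.

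Counts of genes higher and lower, in the order wild-type response, response of the arrays labelled Duox2-/-, genotype in PBS, genotype in flagellin, and difference, changed as follows. At 1.5-fold they were 294 and 71, 124 and 390, 389 and 249, 570 and 816, and 727 and 157. At 3-fold they were 28 and 4, 3 and 16, 46 and 7, 9 and 46, and 50 and 5. With the stricter filter they were 51 and 4, 10 and 32, 52 and 20, 17 and 112, and 72 and 6. With a floor at the median they were 47 and 4, 11 and 33, 47 and 15, 19 and 129, and 86 and 9. With no filter 11 were lower in the wild-type response, 44 higher in the response of the arrays labelled Duox2-/-, 267 higher by genotype in PBS, 95 higher by genotype in flagellin, and 276 and 42 in the difference. With probe sets of several genes kept, 71 were higher by genotype in flagellin. Without muscle, squamous, tooth and gland genes, 4 were lower in the wild-type response and 41 in that of the arrays labelled Duox2-/-. Without receptors 65 and 12 were higher in those responses and 63 and 26 by genotype in PBS and in flagellin.

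In the additive limma model the counts for flagellin were 0 and 0 after cyclic loess (687 at an unadjusted p under 0.05), 52 and 8 with no filter, 80 and 71 with a trended robust prior, 59 and 14 without tissue genes, and 6 and 0 without receptors (684 at an unadjusted p under 0.05); after quantile renormalisation 2 were lower. For genotype they were 1 and 0 after loess (2340 at an unadjusted p under 0.05), 1402 and 477 with no filter, 517 and 943 with the trended robust prior, 142 and 129 after quantile renormalisation, and 490 and 452 without tissue genes. The lowest adjusted p for flagellin ranged from 4.40e-14 with the trended robust prior to 0.0922 after loess. The responder difference was 1.36 for higher genes without receptors, 0.069 for higher genes chosen by the arrays labelled Duox2-/- and -1.06 for lower genes chosen by wild type, which is the opposite sign of the 0.55 by both; choosing by 1 genotype favours that genotype. The other counts of genes past 2-fold, or past the limma threshold in each direction, stayed within 1.5 times those reported. The genes at an unadjusted p under 0.05 for flagellin were 1413 with no filter, against 805, and the olfactory receptors raised were 37 with no filter, 57 with the trended robust prior and 41 without tissue genes, against 23.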

Other observations

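The sets of bone marrow, red cell, epithelial and olfactory zone genes were chosen after seeing the data.

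Genes of the circadian clock were on balance lower after flagellin in both genotypes. The list's median was -0.37 in wild type and -0.23 in the arrays labelled Duox2-/-, and 4 of 15 tested genes passed limma's test for flagellin when adjusted over the list alone, against 0 over all genes (805 of 12471 genes at an unadjusted p under 0.05). In wild type the output gene Dbp was at -0.90, the repressor Nr1d1 at -0.88, Ciart at -0.67 and Bhlhe41 at -0.61. In the arrays labelled Duox2-/- Ciart was at -0.54, Per3 at -0.51, Bhlhe41 at -0.46 and Per1 at -0.43. Not all members shared this: 5 of 15 were above 0 in wild type and 3 of 15 in the arrays labelled Duox2-/-. Nfil3 was at 0.52 and 0.20 in those genotypes, Arntl at 0.45 and 0.07, and Per1 in wild type at 0.19. The time of day at which tissue was taken is not given in the sources used here.

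Vomeronasal receptor genes, dim on these arrays, were higher in the PBS array labelled Duox2-/- than in wild type, with a median of 0.63 over 167 genes and 43 at least 2-fold higher; olfactory receptors had a median of 0.39. After flagellin the vomeronasal receptors had a median of -0.36 in the arrays labelled Duox2-/- and, near 0, of -0.02 in wild type; Vmn2r1 was at -1.79 in the arrays labelled Duox2-/-. Red cell transcripts were lower in the wild-type PBS array than in the other 3. The beta-globin probe sets, each shared by several genes, had log2 values of 11.22 and 11.19 there, 12.03 and 12.02 in wild-type flagellin, 12.01 and 12.05 in PBS labelled Duox2-/-, and 12.13 and 12.14 in flagellin labelled Duox2-/-. Across 8 red cell genes the median response was 0.69 in wild type and 0.08 in the arrays labelled Duox2-/-. Xist was between 10.3 and 10.5 in all 4 arrays, and the Y-linked genes Uty and Eif2s3y were at most 4.53.

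Of the sets chosen later, 15 genes picked as an epithelial response had medians of 0.99 in wild type and 0.43 in the arrays labelled Duox2-/-, 10 bone marrow genes 0.56 and 0.09, and 10 mature neutrophil genes 1.18 and 0.23. Since RNA of the mucosa was measured, the cells that made these transcripts were not tested. Genes of the dorsal olfactory zone were at -0.09 and 0.13, and those of the ventral zones at 0.12 and -0.33, with 4 genes each. Within each set the genes differed in sign. In the arrays labelled Duox2-/- the dorsal genes ranged from -0.09 to 0.25 and the ventral genes from -0.40 to 0.30.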
